A study of Mus musculus with 4 samples.

How the data were processed

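The series holds 4 libraries from sorted CD45-positive brain cells of 2 genotypes: a gene expression library and a T cell receptor library from each. Files of the 2 gene expression libraries were used, and the 2 receptor libraries were not analysed here. Groups were taken from the genotype given in the labels. Per the labels' protocols, brain homogenates were cleared on Percoll, live CD45-positive cells were sorted by flow cytometry, and libraries were made with a droplet kit of 10x Genomics that captures the 5' end of transcripts, named there as Next GEM 5' version 2. Per the submitters' processing notes, Cell Ranger 7.2.0 and the mouse build mm10 were used. The settings of cell calling, the annotation release and whether mice were pooled within a library are not given in the sources used here.

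Each library was represented by 2 text lists as deposited by the authors: the barcodes kept as cells, and the genes against which reads were counted. Neither list carries a numeric value, so no normalization, filter on expression, doublet call, clustering or test of expression was made, and the shares of cell types and the expression comparisons that had been planned for count data could not be computed. The depth of each library is unknown, and the number of cell barcodes is the only quantity per library.

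Barcodes were counted per library. Intervals on counts are exact Poisson intervals at 95% confidence, and the interval on the ratio of the libraries comes from the exact Clopper-Pearson interval of one library's share of all barcodes. They cover counting error only. Barcodes were compared between libraries on all 16 bases. The number expected to be shared by independent draws was the product of the 2 library sizes divided by the size of the list drawn from, and its one-sided p-values are exact hypergeometric. The size of the list was taken in one of 2 ways. For the kit named in the labels it was set to 737280 barcodes, which is general knowledge of that kit and is not from the files. The other size was built from the barcodes themselves: bases 1 to 9 and bases 10 to 16 were treated as segments, and all pairs of observed segments with the same base 9 were counted. A list size was also estimated from the overlap, as the product of the library sizes divided by the number shared. This estimate was tested on simulated data, with 200 simulated pairs of libraries for each list size. Each pair was drawn with equal chance for every barcode of a list of known size. Unequal use of barcodes and the building of a list from segments were not simulated, so the test does not cover them. The median estimate of the list size was 99.5% of the true size for the list built from the segments and 100.3% for the list of the named kit, and the interval covered the true expected number in 98.5% and 96.5% of pairs.

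Gene entries were compared line by line. Of the 32285 gene IDs, 32158 were found in a table of Ensembl IDs and symbols. Positions are those of RefSeq genes on GRCm38.p6, the assembly also known as mm10, matched by symbol, and they are 1-based. Of the 32245 distinct symbols, 38 belonged to more than 1 gene ID. Genes were named by a rule fixed before the data were examined. With no expression values, it named only the Nr4a genes, Cd8a, Cd8b1, Ptprc, App and any transgene entry. The 9 pathway lists and 20 lists of cell type markers were fixed at the same time for use with expression values. Checking their members for gene entries was not part of that rule. The result of 1 pathway list is not reported here. Trac, Trbc1, Trbc2 and the neighbours of Clec7a were named after the lists were seen. Alternatives tried were the count of distinct sequences, leaving out barcodes within 1 base of another, leaving out barcodes found in both libraries, matching on 15 bases, and matching gene entries by symbol alone. Computations used Python 3.11.15, numpy 2.4.6 and scipy 1.17.1.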

Results

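Single-cell libraries were made from live CD45-positive cells sorted from the brains of mice aged 8 months that carried the AppNL-G-F allele, a humanised and mutated amyloid precursor protein knock-in that causes amyloid deposition. CD45 is the surface protein of all leukocytes and is encoded by Ptprc, so the sort can take in microglia, border macrophages and infiltrating lymphocytes. The study compared 2 genotypes, both with floxed Nr4a alleles: controls without Cre, and mice in which Cre under Cd8a control deletes Nr4a in CD8 T cells. The design addresses how loss of Nr4a in CD8 T cells bears on the immune cells of a brain with amyloid. The design lists 5 mice per genotype, but each genotype has 1 gene expression library and 1 T cell receptor library, and the labels tie no barcode to a mouse. Nothing measured here therefore has a replicate.

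The data analysed here are the cell barcodes and the gene entries of the 2 gene expression libraries. UMI counts per cell, cell types, the expression of any gene and the T cell receptor sequences were not analysed here, and the depth per cell is unknown. The efficiency of Nr4a deletion, the state of CD8 T cells and the state of microglia were therefore not measured.

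The control and the Nr4a-deleted library yielded nearly equal numbers of CD45-positive cell barcodes. The control library held 17831 cell barcodes, with an exact 95% Poisson interval of 17570 to 18095. The library from mice with CD8 T cell deletion of Nr4a held 17879, with an interval of 17618 to 18143. The difference was 48 barcodes, and the ratio of the deleted to the control library was 1.0027 with an exact interval of 0.9821 to 1.0238. These intervals cover counting error only, and with 1 library per genotype no test of the genotypes was possible. The number of barcodes called as cells also follows the number of sorted cells loaded, so the ratio does not measure the abundance of immune cells in the brain.

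The labels name the deleted gene as Nr4a without saying which family member. All 3 members had 1 entry each in the list of counted genes of both libraries. Nr4a1 (ENSMUSG00000023034), an immediate early nuclear receptor gene induced by T cell receptor signalling, lies on chromosome 15 from 101253902 to 101274795 (GRCm38.p6). Nr4a2 (ENSMUSG00000026826) lies on chromosome 2 from 57106830 to 57124003, and Nr4a3 (ENSMUSG00000028341) on chromosome 4 from 48045078 to 48086447. Cd8a (ENSMUSG00000053977), whose regulatory sequence drives the Cre, lies on chromosome 6 from 71373427 to 71379171. Its partner chain gene Cd8b1 (ENSMUSG00000053044) lies nearby on chromosome 6 from 71322788 to 71337492. Ptprc (ENSMUSG00000026395), the gene of the sorted marker CD45, lies on chromosome 1 from 138062859 to 138175756. App (ENSMUSG00000022892), the knock-in locus, lies on chromosome 16 from 84952666 to 85175255. All 7 are annotated as protein-coding, and the positions span whole genes, exons and introns included.

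Both libraries were counted against one gene list. All 32285 lines, with their gene ID, symbol and type, were identical between the libraries, and every line had the type Gene Expression and a mouse Ensembl ID. The list had 0 entries named for Cre recombinase, so transcripts of the transgene had no row of their own to be counted in, and the humanised App allele had no entry apart from mouse App. For antigen receptors the list held 200 alpha and delta chain segments of the T cell receptor, 53 beta chain segments and 15 gamma chain segments, among them the constant genes Trac, Trbc1 and Trbc2. It also held 392 immunoglobulin segments, which mark B lineage cells when expressed, and 13 mitochondrial genes.

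The genes that would describe these cells were nearly all countable. Of 120 marker and pathway genes fixed before the data were examined, 119 had an entry. The exhaustion list, with Pdcd1, Tox, Havcr2 and Lag3, had entries for 8 of 8 genes, and the effector list, with Gzmb, Gzmk, Prf1 and Ifng, for 10 of 10. The tissue residency list, with Itgae, Cd69 and Cxcr6, had 6 of 6, and the immediate early list, with Fos and Egr1, had 6 of 6. The homeostatic microglia list, with P2ry12 and Tmem119, had 5 of 5. Of the lists whose genes are not specific to microglia, the interferon list, with Ifit1 and Isg15, had 6 of 6, and the antigen presentation list, with B2m and H2-Ab1, had 6 of 6. The disease-associated microglia list, with Apoe, Trem2, Cst7 and Lpl, had 8 of 9. The absent gene was Clec7a (ENSMUSG00000079293), which encodes the beta-glucan receptor dectin-1 and is a widely used marker of plaque-associated microglia. Of the 20 cell type marker lists, from microglia, macrophages and monocytes to B cells, T cell subsets and NK cells, 19 were complete, and the list for disease-associated microglia had 4 of 5 genes, again without Clec7a. These are counts of annotation entries and carry no expression level.

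The barcode lists of the control and the Nr4a-deleted library were largely different. They shared 99 barcode sequences, with an exact 95% Poisson interval of 80.5 to 120.5, and together held 35611 distinct sequences. Independent draws from the barcode list of the kit named in the labels would share 432.4 sequences, and the one-sided exact hypergeometric p of 99 or fewer was 3.3e-86. Independent draws from the list of 3684480 barcodes spanned by the observed barcode segments would share 86.5, and the one-sided exact hypergeometric p of 99 or more was 0.0998. The size of the kit's list is general knowledge. That size, like the second list, was chosen after the overlap was seen. These tests compare the barcode lists and say nothing about the genotypes. Within each library all barcodes were distinct and carried 1 common suffix.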

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

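The alternatives run could move the counts little or not at all, so they do not show how firmly the counts hold. All barcodes of a library were already distinct, so counting distinct sequences had to leave 17831 and 17879 in the control and the Nr4a-deleted library. Leaving out barcodes found in both libraries could remove only the 99 shared ones and gave 17732 and 17780. Another 2 settings could change nothing, because the first 9 bases of the observed barcodes, and likewise their last 9 bases, were either identical or differed at 2 or more positions. Matching on the first 15 bases therefore had to give the same 99 shared barcodes, and leaving out barcodes within 1 base of another removed 0 barcodes. Neither says anything about sequencing errors. By symbol alone, 32245 gene entries were shared, which is the number of distinct symbols in the list. The other settings intended for cell class shares and for expression (filters on UMIs and mitochondrial share, and another scaling) were not run, since no expression values were analysed here. With 1 library per genotype no replicate could be left out. No paired analysis was possible because each genotype has 1 gene expression library.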

Other observations

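Clec7a, the dectin-1 gene and the only one of the 120 listed genes without an entry, was looked up by both its symbol and its ID, and neither occurred in the gene list of either library. RefSeq places it on chromosome 6 from 129461591 to 129472785 (GRCm38.p6) as a protein-coding gene with 1 coding and 1 non-coding transcript. All of its 10 nearest protein-coding genes, 5 on each side, had an entry. They include Clec12a, Clec9a, a marker of conventional dendritic cells, and Klrd1, a receptor gene of NK cells and CD8 T cells. A count table built on this list has no row for Clec7a, so a plaque-associated microglial state would have to be read there from other members such as Cst7, Itgax and Lpl. Why the gene has no entry was not tested.

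The comparison with the kit's list was fixed before the data were examined, while the list size it used, its bound, the first-base test, the list built from segments and the carry-over test were chosen after the number of shared barcodes was seen. The libraries shared 99 barcodes, far fewer than the 432.4 that independent draws from the barcode list of the kit named in the labels would give (hypergeometric p of as few or fewer, 3.3e-86). Removal of shared barcodes from lists of that kit is argued against by the first base: 0 of 35710 barcodes started with T, which allows a share of up to 0.0084%, while that kit's list holds barcodes starting with T. That last premise, like the size of that list, is general knowledge of the kit and does not come from the files. The barcodes had a regular structure, with 3840 different first segments and 3838 different last segments, and only 4 pairs of bases occurred at positions 8 and 9. Pairing the observed segments spans a list of 3684480 barcodes. Independent draws from it would share 86.5, inside the interval of 80.5 to 120.5 around the observed number. The overlap alone gave a list size of 3220207 (95% interval 2645011 to 3962109). This estimate restates the same comparison and is not separate support. A candidate explanation, which was not tested, is that the cells were captured on beads of another generation than the labels name. The later GEM-X 5' chemistry of the same maker is named only from general knowledge. Its list was not used here for comparison. Whether Cell Ranger 7.2.0, the version in the submitters' processing notes, accepts barcodes of that chemistry was not checked. No biological explanation was tested, since barcodes belong to beads and not to cells.

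Carry-over of barcodes between the libraries stayed open. The excess of shared barcodes over independent draws from the spanned list was 12.5, with an upper limit of 34.0. The interval of the observed number, 80.5 to 120.5, included the expected 86.5, so the absence of any excess was not excluded. The one-sided hypergeometric p of as many or more was 0.0998. Those draws take every barcode of the spanned list as equally likely, which was not tested. The excess is therefore not a measure of carry-over alone.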
